A study of Mus musculus with 6 samples.

How the data were processed

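CD31-positive cells were sorted by flow cytometry from dissociated LLC tumours 2 weeks after subcutaneous injection of the tumour cells, and RNA was isolated with a kit for small cell numbers, per the labels' protocols. Libraries were made with an amplicon panel for mouse transcripts (Ion AmpliSeq Transcriptome) and sequenced on an Ion Torrent instrument, per the labels' protocols. Such a panel amplifies 1 short segment per gene by PCR, so amplicon yield differs between genes and levels of different genes are only roughly comparable. It does not see reads outside the targeted segment. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and any filter are not given in the sources used here.

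The deposited values are RPM, scaled by the authors to the reads of each library, as the header and values of the table show, since the values of each of the 6 columns sum to the scale the unit names. Within a library all values were whole multiples of the value of 1 read. Whole reads were recovered for 100% of the nonzero values within 0.05 reads (largest deviation 0.015 reads), which gave the library depths and allowed count tests as alternatives. Reads are PCR copies without molecular identifiers, so floors cover counting error only. Confidence intervals of fold changes rest on the spread between libraries in the limma fit. RPM is relative: when some abundant transcripts rise, others fall in share.

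Groups and replicate numbers came from the sample titles. All 6 libraries entered the comparison, 3 per group. The descriptions carry run time stamps, with control replicates 1, 2 and 3 and BMP9 replicate 4 under the earlier and BMP9 replicates 5 and 6 under the later. The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(RPM + 1), without further scaling, for genes with at least 5 RPM in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this test unless another tool is named. Fold changes are differences of mean log2(RPM + 1), BMP9 overexpression minus control. Gdf2 was tested by an exact two-sided permutation test.

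A total of 32 gene lists (451 distinct genes, of which 25 had no match in the table) were fixed before the data were examined: signalling and vessel lists, metabolic and stress lists, and markers of the cell types a CD31 gate on a tumour could hold. The 24 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over these lists, beside camera with an estimated correlation and fry. Some genes stand in more than 1 list, and several markers are shared between cell types. Named genes were chosen by a rule fixed at the same time. They were Gdf2 and the measured BMP-SMAD targets, the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean of at least 10 RPM and no overlap of groups, up to 4 tested members with the smallest p of each list, and Pecam1. A side with fewer than 12 was to be filled from genes of unadjusted p under 0.01, which was not needed. Some genes that the rule names are not reported here. Cdh5, Tek, E2f1, Ms4a7, Mmp9, Hk1, Foxo1, Cd74, H2-Eb1, Prf1, Cd3d and Actb were chosen after their values were seen. Gene coordinates and biotypes are those of GENCODE M21 on the mm10 build and give the whole gene. Positions of the amplicons were not used here.

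On simulated reads with the depths of this comparison and 1 common dispersion of 0.078 (9341 genes tested), the procedure recovered 16.2% of 2-fold and 95.9% of 4-fold changes. Of its calls 2.7% were false, and 0 calls were made with no change simulated. Only 99 tested genes were changed 2-fold and 97 4-fold, whereas 3330 genes were called in the data. The adjusted threshold is stricter when fewer genes change. These shares therefore do not measure how many changes near 2-fold were missed here. When only the hypoxia-response list was raised 2-fold in simulated reads, camera with the preset correlation also called 1 other list, which shares members with it.

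Alternatives planned before the data were examined were pseudocounts of 0.5 and 5, no filter, a filter of mean RPM of at least 20, TMM factors, quantile normalization, array weights, no trend, the run time stamp as a covariate, the earlier stamp alone, leaving out each library, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, and for lists an estimated correlation and fry. Thinning all libraries to the reads of the shallowest was added after seeing the data. edgeR called 3114 and DESeq2 3317 genes.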

Results

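Transcript levels were measured in CD31-positive cells sorted from subcutaneous tumours grown in C57/Bl6 mice from Lewis lung carcinoma (LLC) cells, a mouse lung cancer line. CD31, encoded by Pecam1, is an adhesion molecule of endothelial cells that platelets and many leukocytes also carry. The injected LLC cells either overexpressed BMP9, a circulating ligand of the bone morphogenetic protein family that signals in endothelial cells through the receptor ALK1 (Acvrl1), or were controls. The title of the series names BMP9 signalling and the normalization of tumour blood vessels as its subject, and the design has 1 comparison, of 3 BMP9 overexpression libraries (replicates 4, 5 and 6) with 3 control libraries (replicates 1, 2 and 3). The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The values were RPM (reads of a gene scaled to the total reads of the library) for 23930 genes, from an amplicon panel that reads a short segment of each gene.

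The control libraries held 4583428, 1321762 and 1999786 reads in replicates 1, 2 and 3. The BMP9 overexpression libraries held 1974510, 4409655 and 28380957 reads in replicates 4, 5 and 6. A level of 3 reads corresponded to 0.655, 2.27 and 1.5 RPM in the control libraries and to 1.519, 0.68 and 0.106 RPM in the BMP9 libraries, and such floors cover counting error only. Between 12316 and 16883 genes had reads in a library. The 10 most abundant genes took between 6.65% and 10.05% of the reads, and Actb was the most abundant gene in all 6 libraries. Across tested genes, which are not independent replicates, Pearson's r of log2(RPM + 1) was 0.935 to 0.968 between control libraries, 0.903 to 0.964 between BMP9 libraries and 0.762 to 0.84 between libraries of different groups. Reads of every pair of libraries differed by more than sampling noise, with a chi-square of at least 9.2 per degree of freedom, so no pair was treated as 1 library deposited more than once. Repeat libraries of 1 sample would also differ by more than that noise.

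The transcript of BMP9 itself, Gdf2 (chromosome 14, 33941039 to 33947198, mm10), was close to the limit of detection in the sorted cells. Control libraries held 0 Gdf2 reads of 7904976, which allows a level of up to 0.38 RPM. BMP9 overexpression libraries held 7 Gdf2 reads of 34765122, with 1, 1 and 5 reads in replicates 4, 5 and 6. The mean difference was 0.37 on the log2(RPM + 1) scale with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Given that 18.5% of all reads came from control libraries, the exact binomial p of the read split was 0.36. Overexpression was in the injected tumour cells and not in the sorted population, so these reads do not measure it, and no fold is given.

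Pecam1 (chromosome 11, 106654217 to 106750628), the gene of the sort marker, was at 448 ± 84.3 RPM in control and 303 ± 53.5 RPM in BMP9 libraries (SD, n = 3 each), a log2 fold change of -0.56 (SE 0.27) that did not pass the test (limma adjusted p = 0.12) and was -0.84 within the earlier run time stamp and -0.32 with TMM scaling. That the libraries hold the CD31-positive fraction rests on the labels, and no other sorted fraction was analysed here. The other 23 pan-endothelial markers were far lower. Their median was 1.09, 3.03 and 2 RPM in control replicates 1, 2 and 3 and 1.52, 0.23 and 0.56 RPM in BMP9 replicates 4, 5 and 6. That median was between 0.06% and 0.68% of the Pecam1 level of the same library. Their sum was 125 ± 20.1 RPM in control and 140 ± 5.26 RPM in BMP9 libraries (SD, n = 3 each), or 25% to 31.4% and 38.8% to 55.2% of Pecam1. Eng, a receptor that macrophages also express, gave the largest part of it, with 48.2 and 78.4 RPM. Cdh5, the junctional VE-cadherin of endothelial cells, was at 9.81 RPM in control and 6.15 RPM in BMP9 libraries on average. Transcripts of leukocytes were abundant in the same libraries. The 14 T and NK cell markers together summed to 6020 ± 153 RPM in control and 1110 ± 330 RPM in BMP9 libraries, and the macrophage and monocyte markers to 6520 ± 1380 and 24500 ± 3030 RPM (SD, n = 3 each).

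**Figure D1:**
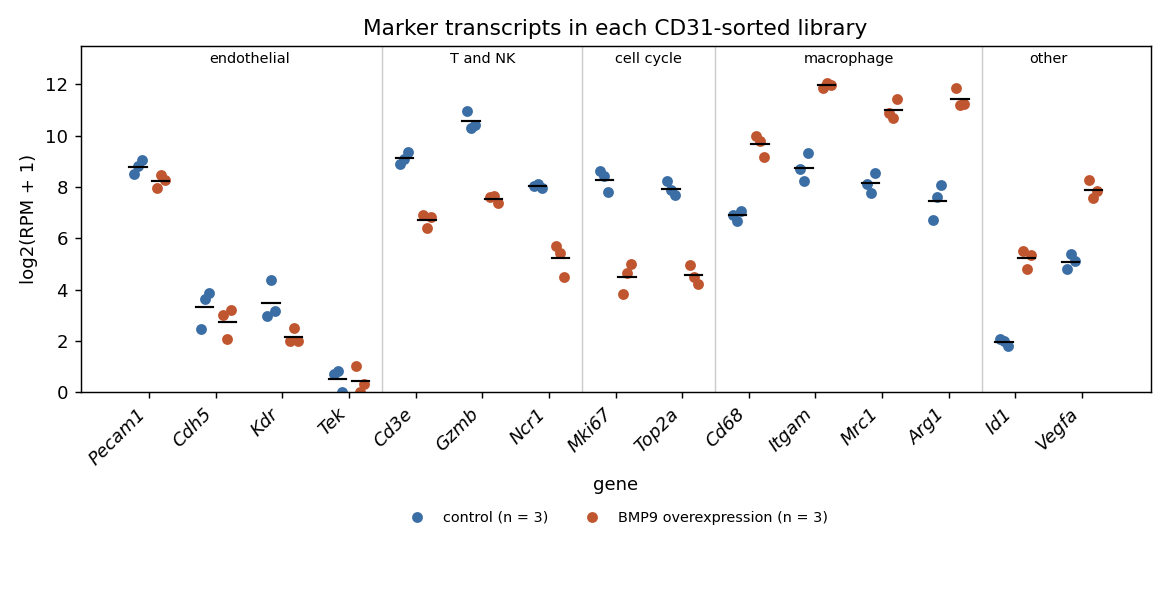
Level of 15 marker genes in each library, as log2(RPM + 1) on the vertical axis; points are libraries (3 control, 3 BMP9 overexpression) and black lines are group means. T and NK cell and cell cycle markers lay lower, and macrophage markers higher, in all 3 BMP9 libraries than in all 3 control libraries, while Cdh5, Kdr and Tek lay near the lower end of the scale in both groups.

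Of 9460 genes tested, 3330 (35.2%) passed an adjusted p of 0.05 (limma-trend), 1200 higher and 2130 lower in BMP9 overexpression libraries. Among the called genes, 1009 were over 2-fold higher and 1712 over 2-fold lower, and 69 and 87 were over 8-fold higher and lower, all on the log2(RPM + 1) scale, which understates changes of low genes. Groups did not overlap for 3235 of the called genes and for 4546 (48.1%) of all tested genes, where chance gives 10%. The first principal component held 68.6% of the variance and separated the groups, with control libraries at -58.9 to -43.9 and BMP9 libraries at 50.3 to 54.6. The balance of directions depended on the scaling. With RPM as deposited 36% of the calls were higher, against 52.6% with TMM factors (1582 higher, 1424 lower), 50% after quantile normalization, 54.4% with edgeR and 53.4% with DESeq2 on recovered reads. The median log2 fold change of all tested genes was -0.24 as deposited and -0.01 with TMM, and changes below are to be read relative to that shift. Array weights, which weight libraries by their fit, raised the count to 5102, and leaving out control replicate 1 brought the number of lower genes to 1367. BMP9 replicate 4 was sequenced under the same run time stamp as the 3 control libraries, and BMP9 replicates 5 and 6 under a later one that holds no control. Within the earlier stamp 2641 genes were called (976 higher, 1665 lower), and 2990 with the stamp as a covariate. Both settings compare BMP9 replicate 4 alone with the controls and give the same folds, so they are 1 contrast and not separate evidence. They differ in the spread, which comes from the 3 controls within the earlier stamp and from the controls with BMP9 replicates 5 and 6 under the covariate, and replicate 4 is assumed to vary like those libraries.

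On the log2(RPM + 1) scale the 12 genes with the largest increase were led by Mmp13, Inhba and Lyve1. Their order depends on the pseudocount, as Inhba and Lyve1 were at only 0.889 and 0.958 RPM in control libraries. Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), was at 0.791 ± 0.753 RPM in control and 100 ± 5.17 RPM in BMP9 libraries (SD, n = 3 each), a log2 fold change of 5.92 (SE 0.38, adjusted p = 8.6e-07). Inhba, the subunit of activin A (chromosome 13, 16011851 to 16031621), rose by 5.37 (SE 0.43), and Lyve1, a hyaluronan receptor of lymphatic endothelium and of some macrophages (chromosome 7, 110850607 to 110863239), by 5.33 (SE 0.41). Cd163, a haemoglobin scavenger receptor of macrophages, rose by 4.69 (SE 0.51), and Mmp8, the neutrophil collagenase, by 4.48 (SE 0.42). The next were Fcna (4.13), Retnla (4.07), Arg2 (4.02), Arg1 (3.96), Il1a (3.95), Pdpn (3.92) and Cxcl1 (3.91). Arg1, an arginine-degrading enzyme of myeloid cells (chromosome 10, 24915221 to 24927484), went from 189 ± 82.2 to 2810 ± 755 RPM, the highest level among these genes. Within the earlier run time stamp the log2 fold changes of Mmp13, Inhba, Lyve1 and Arg1 were 5.91, 6.31, 5.3 and 4.38. With a pseudocount of 5 in place of 1, those of Arg2, Il1a and Cxcl1 were 2.49, 2.59 and 2.51. Macrophage and monocyte markers (median 2.36) and immediate-early and heat shock genes, which respond to tissue dissociation (median 1.04), were higher in the same libraries.

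On the log2(RPM + 1) scale the 12 genes with the largest decrease were led by Gzmc, Nusap1 and Gzmf. This order depends on the pseudocount, as Gzmf was at only 1.74 ± 1.14 RPM in BMP9 libraries. Gzmc (chromosome 14, 56231441 to 56234656), a granzyme of cytotoxic lymphocytes, went from 788 ± 172 RPM in control to 38.3 ± 15.6 RPM in BMP9 libraries, a log2 fold change of -4.38 (SE 0.31, adjusted p = 1.6e-06). Gzmf and Gzme changed by -4.20 and -3.90. Klrd1, the CD94 subunit of NK cell receptors, changed by -3.76. Of the mitotic genes, Nusap1, a spindle protein, changed by -4.24 (SE 0.35), Espl1, the separase that releases sister chromatids, by -4.0, Mki67, the proliferation antigen Ki-67 (chromosome 7, 135689784 to 135716361), by -3.79 (SE 0.34), and Kif4, a kinesin, by -3.74. The histone genes Hist1h2bb, Hist1h2ab and Hist1h1d changed by -4.10, -3.99 and -3.75. Gm4759, annotated as an unprocessed pseudogene, changed by -4.0. Granzyme and histone genes and some killer cell lectin-like receptor genes have near-identical copies and Gm4759 is a pseudogene, so which gene gave their reads is uncertain. Within the earlier stamp the changes of Gzmc, Nusap1 and Mki67 were -3.78, -4.7 and -4.46, and with a pseudocount of 5 those of Espl1 and Kif4 were -2.31 and -2.38.

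**Figure D2:**
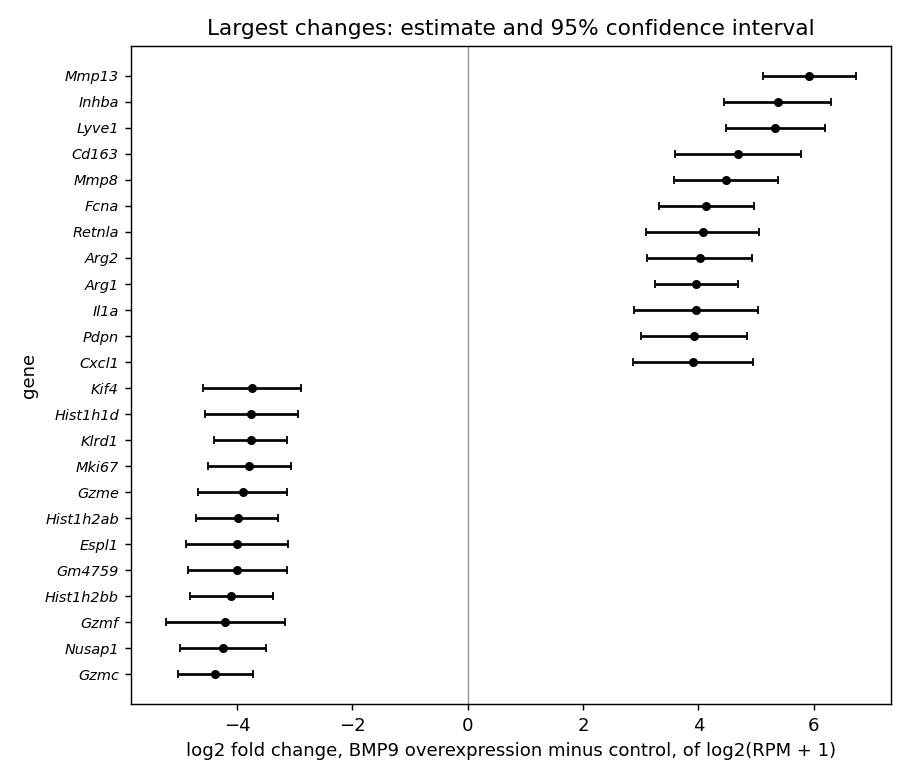
Log2 fold change (BMP9 overexpression minus control, log2(RPM + 1) scale, horizontal axis) of the 12 genes with the largest increase and the 12 with the largest decrease; points are estimates and bars 95% confidence intervals from 3 libraries per group. Estimates run from -4.38 for Gzmc to 5.92 for Mmp13.

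Markers of T and NK cells were lower in BMP9 overexpression libraries. All 14 fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of -2.83 (camera adjusted p = 4e-09; adjusted p = 0.19 with an estimated correlation). Gzmb, the granzyme B of cytotoxic cells, went from 1550 ± 378 to 188 ± 19.4 RPM (-3.02, SE 0.27, adjusted p = 3.6e-06), and Gzma changed by -3.11 (SE 0.34). Cd3e, a chain of the T cell receptor complex, went from 560 ± 89.5 to 105 ± 18.4 RPM (-2.41, SE 0.26), and Ncr1, the NK cell receptor NKp46, from 262 ± 16.1 to 38.5 ± 15.2 RPM (-2.82, SE 0.31). The list median was -2.60 with TMM and -2.24 within the earlier run time stamp.

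Cell cycle genes were lower in the same libraries. Of 28 tested members 27 fell, also when adjusted over the list alone, and E2f1, a transcription factor of S phase entry, had a log2 fold change of -0.61 (adjusted p = 0.14), or -0.38 with TMM, and its call was gained with array weights (-0.84). The median was -2.53 (camera adjusted p = 5.4e-17; adjusted p = 0.082 with an estimated correlation), with -2.31 under TMM and -2.20 within the earlier stamp. Mki67 went from 320 ± 89.0 to 22.8 ± 9.09 RPM, Top2a, a topoisomerase of dividing cells, from 247 ± 49.4 to 23.3 ± 6.44 RPM (-3.37, SE 0.29), and Birc5, the survivin of mitosis, from 167 ± 15.1 to 21.8 ± 0.0821 RPM (-2.87, SE 0.26). T and NK cell markers moved in the same direction, as given above.

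Macrophage and monocyte markers were higher in BMP9 overexpression libraries. Of 15 tested members 14 rose, also when adjusted over the list alone, with a median of 2.36 (camera adjusted p = 2.4e-13; adjusted p = 0.08 with an estimated correlation), and Ms4a7 had a log2 fold change of 0.55 (adjusted p = 0.18), or 0.25 within the earlier stamp, and its call was gained with array weights (0.67). Itgam, the integrin CD11b of myeloid cells, went from 451 ± 170 to 4010 ± 296 RPM (3.21, SE 0.31, adjusted p = 5.6e-06). Mrc1, the mannose receptor CD206, went from 292 ± 80.7 to 2100 ± 595 RPM (2.84, SE 0.30), and Cd68, a lysosomal protein of macrophages, from 119 ± 16.6 to 831 ± 230 RPM (2.77, SE 0.28). The median was 2.59 with TMM and 2.77 within the earlier stamp.

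Of 7 tested neutrophil markers 6 rose and Mmp9, a gelatinase, fell by 1.56 on the log2 scale (adjusted p = 0.0016), with the same counts adjusted over the list alone and a median of 1.76 (camera adjusted p = 0.00012; adjusted p = 0.08 with an estimated correlation) that was 1.87 within the earlier stamp. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, rose by 3.38 (2.19 with a pseudocount of 5) and 3.47 but reached 25 ± 5.18 and 84.2 ± 56.5 RPM. The remaining 5 of the 12 measured neutrophil markers were below the filter. All 12 summed to 209 RPM in control and 561 RPM in BMP9 libraries, of which Il1r2 gave 94.6 and 252 RPM. The 3 tested platelet and megakaryocyte markers, too few for a list test, rose over all genes and adjusted over the list alone. The other 5 of the 8 measured were below the filter. Over all 8 the median of the member means was 0.318 RPM in control and 1.86 RPM in BMP9 libraries. Pf4 gave most of their sum of 57.6 and 689 RPM, so a change in platelets cannot be read from this list. Pf4, platelet factor 4, went from 49.1 ± 16.7 to 619 ± 113 RPM (3.68, SE 0.30), Ppbp rose by 3.90 and Itga2b by 2.01. Dendritic cell markers did not pass as a list, with 2 of 8 lower on both adjustments (median -0.42, camera adjusted p = 0.69), and 1 was lower without control replicate 1 or with the run time stamp as a covariate and 1 higher without BMP9 replicate 4 or 5 or with DESeq2. B cell markers did not pass either, with 1 of 5 higher on both adjustments, Cd22 (1.58, adjusted p = 0.0045; 0.95 with array weights), and with a median of -0.13, which was 0.09 with TMM, 0.18 after quantile normalization and 0.44 within the earlier stamp, a mean of 0.18 and a test direction of higher (adjusted p = 0.52). Without BMP9 replicate 4, 1 B cell marker was also called lower.

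Genes of inflammation, hypoxia and glycolysis were higher together with the macrophage markers and with immediate-early and heat shock genes, which respond to tissue dissociation (8 of 14 higher, median 1.04). Of 14 tested leukocyte adhesion and chemokine genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 1.18, camera adjusted p = 0.00023; adjusted p = 0.08 with an estimated correlation). The member that fell was Icam2, and the number lower was 0 without control replicate 3 or BMP9 replicate 6, after quantile normalization (8 higher) and with the stamp as a covariate (7 higher), and 2 without BMP9 replicate 4 or 5. With a mean of at least 20 RPM, which leaves fewer members, 4 rose and 0 fell. The members that rose were mostly secreted factors. Ccl2, a monocyte attractant, went from 66.2 ± 13.6 to 537 ± 69.3 RPM (3.01, SE 0.26, adjusted p = 3.5e-06), Il6 rose by 3.04 and Ccl7 by 2.55. Of 18 hypoxia-response genes 11 rose and none fell, or 12 adjusted over the list alone (median 1.11, camera adjusted p = 2.3e-06; adjusted p = 0.08 with an estimated correlation), and 7 rose and 1 fell within the earlier stamp, or 11 and 1 with the stamp as a covariate. Vegfa, the vascular endothelial growth factor (chromosome 17, 46016993 to 46032369), went from 33.7 ± 7.12 to 242 ± 60.6 RPM (2.80, SE 0.29, adjusted p = 9.1e-06), and Hk2, a hexokinase, from 34.7 ± 7.06 to 175 ± 32.6 RPM (2.31, SE 0.28). Of 13 glycolysis genes 6 rose and 1 fell on both the wide adjustment and adjusted over the list alone (median 0.60, camera adjusted p = 0.002; adjusted p = 0.2 with an estimated correlation), among them Slc16a3, a lactate exporter (2.19, SE 0.34), and Slc2a1, the glucose transporter GLUT1 (1.65, SE 0.36; 2.49 within the earlier stamp). With TMM, edgeR or DESeq2 6 glycolysis genes were higher and 0 lower, and after quantile normalization 5 and 0, against 4 and 0 without the filter on low values. The glycolysis gene that fell was Hk1, another hexokinase (-0.81, SE 0.28), whose call was lost with TMM (-0.57), with the run time stamp as a covariate (-0.40), and without control replicate 1 (-0.80), 2 (-0.83) or 3 (-0.79) or BMP9 replicate 5 (-0.68) or 6 (-0.72). Within the earlier stamp the medians of the chemokine, hypoxia and glycolysis lists were 1.49, 1.28 and 0.89. The hypoxia and glycolysis lists share several members, among them Hk2 and Slc2a1, so their results are not separate evidence.

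TGF-beta and mesenchymal transition genes passed with 4 of 8 higher and 1 lower, or 5 and 1 adjusted over the list alone (median 1.16, camera adjusted p = 0.0031; adjusted p = 0.1 with an estimated correlation). Tgfbi, an extracellular matrix protein induced by TGF-beta, went from 1590 ± 170 to 7220 ± 382 RPM (2.19, SE 0.29), and Fn1, fibronectin, from 1200 ± 341 to 4470 ± 918 RPM (1.92, SE 0.32), whereas Zeb1, a transcriptional repressor, fell by 1.79 on the log2 scale. Macrophages also express Tgfbi and Fn1, and macrophage markers were higher in the same libraries. Immediate-early and heat shock genes passed with 8 of 14 higher on both adjustments, or 3 higher without the filter on low values (median 1.04, camera adjusted p = 7.7e-05; adjusted p = 0.2 with an estimated correlation), including Atf3 (2.43, SE 0.30), Fos (1.42, SE 0.29) and Hspa1b (1.64, SE 0.28), the last of which has a near-identical copy. Within the earlier stamp the medians of these lists were 1.82 and 1.52.

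Targets and feedback genes of BMP-SMAD signalling were higher on balance. Of 11 tested members 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (median 1.03, camera adjusted p = 0.00098; adjusted p = 0.082 with an estimated correlation), and the median was 1.02 within the earlier stamp. Id1, a direct BMP target that inhibits differentiation factors (chromosome 2, 152736251 to 152737410), went from 2.93 ± 0.395 to 37.4 ± 9.35 RPM (3.26, SE 0.35, adjusted p = 1.2e-05; 3.56 within the earlier stamp), the largest change of the list. Macrophage and monocyte markers (median 2.36) and immediate-early and heat shock genes (median 1.04, 8 of 14 higher) were higher in the same libraries. Sgk1, a kinase, went from 37.2 ± 5.07 to 148 ± 28.1 RPM (1.96, SE 0.28, adjusted p = 9.2e-05), and Hes1, a Notch target as well, from 4.97 ± 1.69 to 19.9 ± 2.91 RPM (1.84, SE 0.36, adjusted p = 0.0012). Id3 (1.24), Jag1 (1.06), Bambi (1.03) and Bmpr2 (0.91) were also called higher, and Id2 (-1.11) and Lfng (-0.85) lower, with adjusted p between 0.011 and 0.044. Id2 is also abundant in NK cells, whose markers fell. Smad7 (0.52, adjusted p = 0.2) and Eng (0.68, adjusted p = 0.063) did not pass. Smad7 was called with the run time stamp as a covariate (1.02) and with DESeq2 (0.80), and was 0.27 without BMP9 replicate 4, and Eng was called with TMM (0.91), quantile normalization, array weights, edgeR and DESeq2. Smad6, Smad9, Tmem100, Atoh8, Hey1 and Hey2, several of them endothelial BMP9 targets, were below the filter on low values in both groups and were not tested. Of these only Smad6 did not overlap between the groups, at 0.458 ± 0.438 RPM in control and 2.65 ± 1.22 RPM in BMP9 libraries. It had 4, 0 and 1 reads in control replicates 1, 2 and 3 and 8, 8 and 59 in BMP9 replicates 4, 5 and 6. The floor of 3 reads in control replicate 2 was 2.27 RPM, above the Smad6 levels in BMP9 replicates 5 and 6 (1.81 and 2.08 RPM). The groups are therefore not resolved for Smad6. The calls of Id3, Jag1, Bambi, Bmpr2, Id2 and Lfng were not firm. Jag1, Bambi, Bmpr2 and Lfng lost theirs with the run time stamp as a covariate (1.02, 0.59, 0.33 and -0.80) and Id2 and Lfng lost theirs with TMM (-0.88 and -0.61) and edgeR (-0.62 and -0.59), Id2 also with quantile normalization (-1.09), DESeq2 (-0.63) and no trend (-1.11). Id3 lost its call with array weights (0.53). The fold of Id2 was -2.36 with the stamp as a covariate and -0.71 with array weights, and that of Bambi 0.68 with a pseudocount of 5 and 1.56 with edgeR. All but Jag1 and Lfng lost theirs without the filter on low values, which leaves each fold as it is and raises the number of genes tested from 9460 to 18274. Bambi and Id2 lost theirs after thinning, with folds close to those of all reads (1.04 and -1.09). The list had 8 members higher and 0 lower with TMM or edgeR, 8 and 1 after quantile normalization, 9 and 1 with DESeq2, 5 and 1 with the stamp as a covariate, 4 and 1 within the earlier stamp or without the filter, and 4 and 2 with a mean of at least 20 RPM. The number of members higher was 4 without control replicate 1 or BMP9 replicate 5, and the number lower was 0 without control replicate 1 or 3 and 1 without control replicate 2 or BMP9 replicate 4 or 5. Calls were lost when single libraries were left out: that of Id3 without control replicate 2 (0.93) or BMP9 replicate 4 (0.96) or 5 (1.18), that of Jag1 without control replicate 1 (1.0), and that of Bambi without control replicate 1 (0.97) or 3 (0.98) or BMP9 replicate 5 (0.84) or 6 (1.01). The call of Bmpr2 was lost without control replicate 1 (0.92), 2 (0.85) or 3 (0.95) or BMP9 replicate 5 or 6 (0.76 each). The call of Id2 was lost without control replicate 1 (-1.02), 2 (-1.13) or 3 (-1.18) or BMP9 replicate 4 (-0.49), and that of Lfng without control replicate 1 (-0.87) or 3 (-0.81) or BMP9 replicate 5 (-0.75).

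Ligands, receptors and SMADs of the BMP and TGF-beta pathways did not pass as a list, with 3 of 16 higher and 3 lower, or 5 and 3 adjusted over the list alone (median 0.10, camera adjusted p = 0.21). The split depended on the scaling, with 5 higher and 0 lower under TMM, edgeR and DESeq2 and 5 and 1 after quantile normalization, and was 3 and 1 with the run time stamp as a covariate. The median turned to -0.05 with the stamp as a covariate or within the earlier stamp, and to -0.03 without control replicate 2. The number higher was 1 without control replicate 1 or 2 or BMP9 replicate 6, and the number lower was 0 without control replicate 3 and 1 without control replicate 1 or BMP9 replicate 5 or 6. Acvrl1, the BMP9 receptor ALK1, went from 8.99 ± 5.99 to 30 ± 13.1 RPM (1.77, SE 0.47, adjusted p = 0.0086; 2.42 within the earlier stamp), and this call was lost without the filter on low values, at the same fold.

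The markers of endothelial cells gave few testable genes. Of 24 pan-endothelial markers 17 were below the filter, and of the 7 tested 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (median -0.56, camera adjusted p = 0.93). With TMM 2 were higher and 1 lower, after quantile normalization 2 and 0, and with edgeR or DESeq2 2 and 2. The number lower was 1 without any 1 of the control replicates and 0 without BMP9 replicate 6. The growth factor receptor Flt1 was higher (1.83, SE 0.45), the receptor Kdr lower (-1.32, SE 0.43) and the adhesion molecule Icam2 lower (-1.20, SE 0.36), at mean levels of at most 21.1 RPM. Which cells gave the reads of these genes was not tested. The calls of all 3 were lost with the run time stamp as a covariate (1.28, -1.48 and -1.23) and, at the same folds, without the filter on low values, that of Kdr (-0.86 with a pseudocount of 5) also with TMM (-1.13) and quantile normalization (-0.92) and without control replicate 2 (-0.89) or BMP9 replicate 6 (-1.23), and that of Icam2 after quantile normalization (-0.89) and without control replicate 1 (-1.04) or 3 (-1.08) or BMP9 replicate 6 (-1.07). Capillary markers did not pass, with 3 of 6 higher, or 3 higher and 1 lower adjusted over the list alone (median 0.58, camera adjusted p = 0.13), and the increase of Cd36, a fatty acid receptor that macrophages and platelets also express, was the largest (3.72, SE 0.37). Without control replicate 1 or BMP9 replicate 4, 1 capillary marker was called lower. Arterial markers had 4 tested members (1 higher, 1 lower), venous markers 2 (Vcam1 and Nrp2, higher) and lymphatic markers 3 (Lyve1 and Pdpn higher, Thy1 lower), with the same counts adjusted over the list alone and no list test. The values of Vcam1, an adhesion molecule, overlapped between the groups, and its call (1.46, SE 0.49) was lost without control replicate 1 (1.38) or 2 (1.05) or BMP9 replicate 4 (1.14) or 5 (1.45), with array weights (0.78) and after thinning (1.25), and was 0.79 with a pseudocount of 5, while that of Nrp2 was lost without the filter on low values, at the same fold (1.52). No arterial marker was called higher without control replicate 1, and none lower without control replicate 1 or 3 or BMP9 replicate 4. With TMM, quantile normalization, edgeR or DESeq2 1 arterial marker was higher and 0 lower, and with the stamp as a covariate 0 and 1. Thy1, which T cells also express, went from 1520 ± 131 to 335 ± 204 RPM (-2.37, SE 0.38; -1.46 within the earlier stamp).

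Lists of vessel growth and vessel maturation did not pass. Tip cell and sprouting genes had 3 of 14 higher and 4 lower on both adjustments, with a median of 0.07, a mean of -0.10 and a test direction of higher (camera adjusted p = 0.52). The number lower was 1 without control replicate 2 or BMP9 replicate 6 and 2 without control replicate 3 or BMP9 replicate 5. The split was 3 higher and 1 lower with TMM, 4 and 2 after quantile normalization, 3 and 2 with edgeR, 4 and 3 with DESeq2 and 4 and 1 with the stamp as a covariate, and the median was -0.17 without control replicate 2. Plaur, the urokinase receptor, rose by 2.34 (SE 0.29) and Trp53i11 fell by 2.24 (SE 0.31). Genes of vessel maturation, junctions and quiescence had 4 of 12 higher and 1 lower on both adjustments (median 0.23, camera adjusted p = 0.069), and the list passed in the contrast of BMP9 replicate 4 alone with the controls, by either use of the stamp (median 0.46), with a mean of at least 20 RPM (0.34) and without control replicate 3 (0.24). These passes rest on the preset correlation, and over all libraries the list had an adjusted p = 0.28 with an estimated correlation. With TMM or edgeR 4 were higher and 0 lower, and with DESeq2 5 and 0. The 4 were Thbd (2.51, SE 0.38), Klf4 (2.30, SE 0.28), Gja1 (2.10, SE 0.38) and F11r (1.64, SE 0.33), none of which is confined to endothelial cells. The member that fell was Foxo1, a transcription factor (-1.26, SE 0.40), whose call was lost with TMM (-1.03), with the stamp as a covariate (-0.34), and without control replicate 2 (-0.97) or BMP9 replicate 5 (-0.83) or 6 (-1.23). The VEGF, angiopoietin and apelin axes had 3 of 7 higher and 2 lower on both adjustments (median 0.41, camera adjusted p = 0.19), and Notch pathway genes 3 of 8 higher and 2 lower (median 0.77, camera adjusted p = 0.16). The number lower in the first was 1 without control replicate 2 or BMP9 replicate 6, and in the Notch list 1 without control replicate 1 or 3 or BMP9 replicate 5. It was also 1 with TMM in both lists, after quantile normalization in the first and with edgeR in the Notch list, each with 3 higher. With the stamp as a covariate it was 0 in both, with 2 and 3 higher. Of 10 basement membrane genes 4 were lower on both adjustments (median -0.70, camera adjusted p = 0.16), and the list passed without BMP9 replicate 4 (-0.96) with the preset correlation, against an adjusted p = 0.7 with an estimated correlation over all libraries. Only 1 was lower without control replicate 2 or 3 or BMP9 replicate 5 or 6, with TMM, edgeR or the stamp as a covariate, and 2 after quantile normalization or with DESeq2. Of its members Sparc, a matrix protein, was the firmest (-1.71, SE 0.34, adjusted p = 0.0013).

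**Figure D3:**
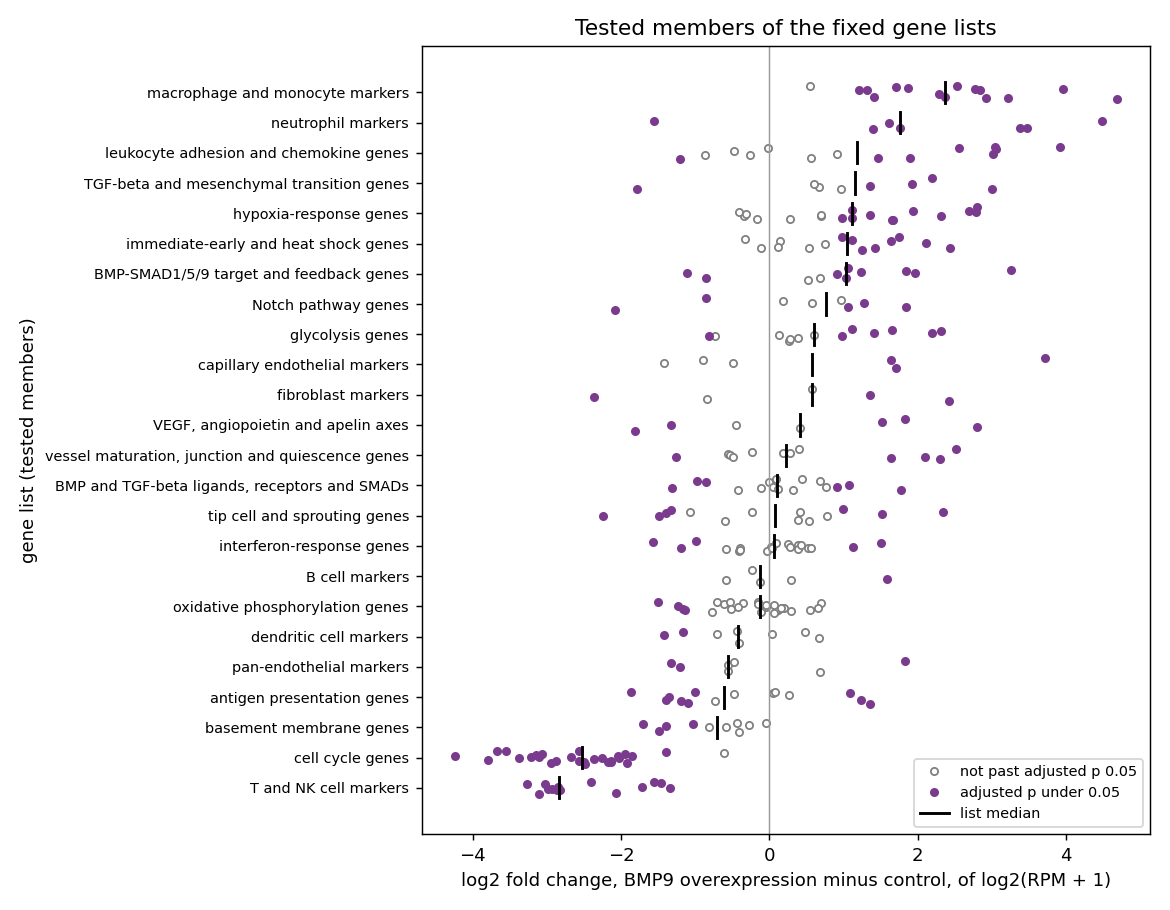
Log2 fold changes (BMP9 overexpression minus control, horizontal axis) of the tested members of the 24 lists with at least 5 tested members, sorted by list median (black bars); filled points passed an adjusted p of 0.05 and open points did not. T and NK cell markers and cell cycle genes lie at the low end, with medians of -2.83 and -2.53, and macrophage and neutrophil markers at the high end, with medians of 2.36 and 1.76.

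Interferon-response genes had 2 of 20 higher and 3 lower, or 2 and 2 adjusted over the list alone (median 0.07, mean 0, camera adjusted p = 0.46), with Rsad2, an antiviral enzyme, higher (1.5, SE 0.35) and Ifit2, an antiviral RNA-binding protein, lower (-1.57, SE 0.40, adjusted p = 0.0073; call lost without BMP9 replicate 6, -1.20). The number higher was 1 without control replicate 1 or 2 or BMP9 replicate 5, and the number lower 1 without control replicate 3 and 0 without BMP9 replicate 6. With TMM, quantile normalization or edgeR 2 were higher and 1 lower, and with DESeq2 3 and 1. The median was -0.06 without BMP9 replicate 4 and -0.04 without BMP9 replicate 5. Antigen presentation genes had 3 of 14 higher and 6 lower on both adjustments (median -0.61, camera adjusted p = 0.62), and among the lower was Tap2, a peptide transporter of the class I pathway (-1.86, SE 0.29, adjusted p = 0.00023). The 3 higher were genes of the class II pathway, Ciita, its transcriptional activator (1.24, SE 0.29), Cd74, the invariant chain (3770 ± 1560 to 9390 ± 2450 RPM, 1.36, SE 0.37), and H2-Eb1 (1.08, SE 0.36; 1.86 within the earlier stamp), a member of a family with near-identical copies. Other class II genes of the list were not called higher. Macrophage and monocyte markers were higher in the same libraries (14 of 15, median 2.36). The call of Ciita was lost with the stamp as a covariate (0.92), that of Cd74 without control replicate 1 (1.10), and that of H2-Eb1 after quantile normalization (0.95) and without control replicate 1 (0.86) or 2 (1.04) or BMP9 replicate 4 (0.69). The number higher was 1 without control replicate 1, and the number lower 3 without BMP9 replicate 6. After quantile normalization 2 were higher and 7 lower, and with the stamp as a covariate 2 and 2. Oxidative phosphorylation genes had 4 of 26 lower on both adjustments (median -0.13, or 0.10 with TMM and 0.01 after quantile normalization, camera adjusted p = 0.72), including Ndufb8, a subunit of complex I (-1.50, SE 0.29), and 8 were lower without BMP9 replicate 4. Members were called higher under other settings, with 1 higher and 4 lower under TMM, 3 and 3 with edgeR or DESeq2, 2 and 3 with the stamp as a covariate and 1 and 8 with array weights. Fibroblast markers had 2 of 5 higher and 1 lower on both adjustments (median 0.58, or -0.49 without control replicate 2, camera adjusted p = 0.52), and Dcn, decorin, rose by 2.42 to 10.4 ± 3.24 RPM (1.29 with a pseudocount of 5). The other higher member, Col1a1, a collagen chain (1.36, SE 0.49; 0.87 with a pseudocount of 5), overlapped between the groups and lost its call without control replicate 2 (0.88) or 3 (1.38) or BMP9 replicate 4 or 5 (1.17 each), with array weights (0.43) and after thinning (1.17), and 2 members were lower without control replicate 2. Mural cell markers had 2 tested members, both lower, Kcnj8 (-1.71, SE 0.38; -0.84 with a pseudocount of 5) and Cspg4 (-1.53, SE 0.48), whose call was lost without control replicate 1 (-1.04) or 3 (-1.49) or BMP9 replicate 5 (-1.29), after quantile normalization (-1.20) and with the stamp as a covariate (-1.39). Epithelial and carcinoma markers had 3 tested members (1 higher, 0 without control replicate 3 or BMP9 replicate 6), the keratinocyte, muscle and adipocyte list had 1 (Tnnt3, 1.63, or 1.04 with a pseudocount of 5, its call lost after thinning, 1.24) and the erythroid list had 0, with the same counts adjusted over each list alone.

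In all, 10 of 24 tested lists passed, 8 higher and 2 lower, with the preset correlation of camera. None passed with an estimated correlation, where camera called 0 lists (7 at an unadjusted p under 0.05), against 13 with the directional and 24 with the mixed fry test. Among the 10 lists the estimate ran from -0.132 (neutrophil markers) to 0.44 (T and NK cell markers). Lists with an estimate below the preset value, such as hypoxia-response genes (-0.029), lost their call as well. For such lists the loss does not show correlation between genes as its cause. The setting with an estimated correlation rests on 4 residual degrees of freedom, which leaves little power. For lists with an estimate far above the preset 0.01, such as T and NK cell markers and cell cycle genes (0.225), a part of correlation in the loss cannot be told apart from that low power. Their adjusted p-values by camera with the preset correlation rest on that preset. With the preset correlation, other splits of the same 6 libraries into 3 and 3 called between 4 and 11 lists. Each of them mixes the groups but keeps part of the group difference. Their calls therefore do not measure how many list calls were false. Counts of called members share the correlation between genes and are to be read beside the share over all genes. Of 9460 tested genes 3330 (35.2%) were called, 1200 higher and 2130 lower. Some lists, such as interferon-response genes with 2 of 20 higher and 3 lower, did not exceed that share.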

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

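No paired analysis was possible because the titles number the libraries 1 to 6 and the groups share no number. Thinning to the shallowest library was chosen after seeing the data; all other alternatives were planned. The count of 3330 genes stayed within 1.5 times, between 2311 (without control replicate 1) and 3552 (without BMP9 replicate 4), except with array weights, which called 5102, of them 3351 lower; the cause was not tested. Leaving out single libraries gave 933 to 1240 higher genes, the lowest without BMP9 replicate 6, and 1367 to 2312 lower genes, the lowest without control replicate 1. Of the called genes 100% kept their sign with TMM, quantile normalization, edgeR and DESeq2, and 99.9% with the run time stamp as a covariate; none was called in the opposite direction under the alternatives run. All 10 lists past the threshold stayed past it in the same direction in all 17 refits, with 10 or 11 lists called, but 0 lists passed with an estimated correlation and 24 with mixed fry, which asks another question. The Gdf2 difference was 0.26 to 0.44 without single libraries, 0.66 with a pseudocount of 0.5 and 0.08 with one of 5.

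Of 123 called genes among those checked, 66 were tested and called in every refit. Another 12 kept the call wherever they were tested but lay below a mean of 20 RPM and were not tested in that refit. The other 45 lost the call in at least 1, most often without the filter (37 genes, where 18274 genes were tested), within the earlier stamp (27, with 1 BMP9 library assumed to vary like the others) and with the stamp as a covariate (25, resting on the same library). Reversals concerned lists and genes that had not passed; for a list the test direction turned, and the value is its median. These were the VEGF, angiopoietin and apelin axes without the filter (-0.57); pan-endothelial markers with array weights (-0.47), the stamp as a covariate or the earlier stamp alone (-0.31 each), and without control replicate 2 (-0.41) or 3 (-0.42; range without single libraries -0.72 to -0.21); dendritic cell markers with array weights (-0.09) and without BMP9 replicate 4 (-0.18); antigen presentation (-0.47) and oxidative phosphorylation genes (-0.04) under either use of the stamp, the latter also without BMP9 replicate 6 (-0.03, range -0.24 to -0.03); and fibroblast markers without control replicate 2 (-0.49, range -0.49 to 1.28). Ms4a1 turned with either use of the stamp (0.39), Cd79b with array weights (-0.11) and without control replicate 2 (-0.10, range -0.10 to 0.51), and Notch1 without control replicate 3 (-0.31, range -0.31 to 0.52), without BMP9 replicate 4 (-0.13) and after thinning (-0.06). The cause was not tested. Some list medians turned while the test direction held: those of tip cell genes without the filter (-0.15) and with array weights (-0.09), of vessel maturation genes without the filter (-0.21) and of interferon-response genes with array weights (-0.17). In lists that did not pass, fewer members were called without the filter, with 1 higher and 1 lower for BMP and TGF-beta ligands, tip cell, antigen presentation and fibroblast genes, 1 and 0 for interferon-response genes and the VEGF axes, and 0 and 1 for basement membrane genes and dendritic cell markers. Array weights gave 5 and 3 for the ligands, 2 and 3 for pan-endothelial, 3 and 2 for capillary, 2 and 2 for dendritic, 1 and 1 for B cell and 1 and 2 for fibroblast markers, and 3 and 6 for interferon-response genes. Depth limits low genes: control replicate 2, the shallowest, cannot resolve levels under 2.27 RPM.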

Other observations

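The tests of the gene families and of the T and NK cell, macrophage and endothelial patterns were chosen after the result was seen, and thinning to the shallowest library was added after seeing the data, though before its own result. Gene families grouped by symbol after the data were seen gave further values; 14 families were tested with camera and none passed with an estimated correlation (0 with camera, 8 at an unadjusted p under 0.05), whose adjusted p is given second. The median of proteasome subunit genes turned with TMM (-0.19, or 0.04), with 2 of 34 higher, 7 lower and 25 not past the threshold (adjusted p = 0.67 and 0.71). Solute carrier genes passed as higher with the preset correlation (adjusted p = 0.045 and 0.33), though their median was 0 (0.23 with TMM), with 28 of 163 higher, 24 lower and 111 not past the threshold. Ribosomal protein genes had 6 of 15 lower (-0.79, adjusted p = 0.18 and 0.26) and annexin genes 2 of 8 higher and 1 lower (0.61, 0.0069 and 0.079). Medians of these and the other 10 families, apart from the proteasome and solute carrier genes, kept their sign with TMM and after quantile normalization. Of 13 tested Ccl chemokine genes 8 rose and 0 fell (median 2.55, adjusted p = 3.9e-07 and 0.067), and of 7 Cxcl chemokine genes 4 rose (1.27, 0.00073 and 0.079). Interleukin 1 family genes had 5 of 8 higher (1.57, 0.00018 and 0.079), matrix metalloproteinase genes 5 of 7 higher and 1 lower (2.54, 0.00018 and 0.075), C-type lectin genes 8 of 15 higher and 1 lower (0.89, 9.4e-05 and 0.075) and cathepsin genes, lysosomal proteases, 5 of 11 higher and 1 lower (0.75, 0.0023 and 0.13). All 7 granzyme genes fell (-3.39, 5.1e-07 and 0.079), as did 21 of 24 killer cell lectin-like receptor genes, with 1 higher (-2.62, 1.2e-10 and 0.079), 15 of 16 replication-dependent histone genes (-2.40, 3.6e-08 and 0.11) and 8 of 9 minichromosome maintenance genes (-2.03, 1.1e-05 and 0.079), some of which the cell cycle list also holds. Members of the granzyme, receptor and histone families have near-identical copies, so their single values are uncertain.

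The first pattern is the size of the difference between the groups. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one (3330, with 1200 higher and 2130 lower), and the highest of the others gave 0 by limma (308 at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05. For lists, 3 of the 10 splits called at least as many as the real 10, and the highest other called 11. Every other split mixes the groups, which widens the spread within each side and leaves part of the group difference between them. Few gene calls there were thus fixed in advance, and the list calls there are not a rate of false calls. The run time stamp as the whole source is argued against: of 3371 genes called between the later BMP9 libraries and control replicates 1 and 2, 90% went the same way between BMP9 replicate 4 and control replicate 3, both of the earlier stamp, with a median ratio of changes of 0.71, though only 1 BMP9 library has that stamp. Depth is argued against as well, since 86% of the called genes stayed called in the same direction after thinning to the shallowest library, which leaves a partial effect of the stamp, a chance division of the libraries, BMP9 overexpression in the tumour cells and any unrecorded difference in tumour size, dissociation or sort as open explanations.

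The second pattern is the fall of T and NK cell markers beside the rise of macrophage markers. A lower share of T and NK cells alone would raise all other cell types alike, but macrophage markers lay 2.59 above dendritic and B cell markers (median -0.23) on the log2 scale (permutation p = 0.00012 over genes, which are not independent). A loss of T and NK cells in 1 proportion stays open: their 14 markers fell by between 1.34 (Cd3d) and 3.27 (Prf1), and Cochran's Q of 48 (4.8 in the highest other split) exceeded its chi-square expectation, but that approximation, tried first, does not suit 3 against 3 libraries, and the exact permutation p of 0.1 is the smallest that 10 splits allow. A low Q in the other splits was fixed in advance, since mixing the groups shrinks the folds and widens the spread. Whether cell cycle transcripts were lost together with T and NK cells cannot be told apart from a separate change, since the medians of both lists differed by 0.3 with a 95% bootstrap interval of -0.79 to 0.68 (permutation p = 0.47). The bootstrap and the permutation both drew genes, which are not independent, so neither covers the spread between libraries. That the sorted population in BMP9 tumours may have held fewer cytotoxic lymphocytes and more, or differently activated, macrophages stays an untested hypothesis, which counts of T, NK and CD11b-positive cells within the CD31 gate, not used here, would decide.

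The third pattern is the low level of endothelial transcripts in cells sorted for an endothelial marker. The median of the 23 markers other than Pecam1 was at most 0.68% of Pecam1 in any library, though their sum, led by Eng, was 25% to 55.2% of it, so a candidate explanation is that much of the Pecam1 signal came from leukocytes, which carry CD31 and whose markers were abundant (Itgam 4010 RPM in BMP9 and Gzmb 1550 RPM in control libraries). No gate against leukocytes is given in the labels, and whether the columns could hold another sorted fraction than the one labelled, which would change what every value means, was not tested and stays open. Poor yield of the endothelial amplicons cannot be excluded, as at least 3 reads were seen for 10 of the 24 in the poorest library and 21 in the deepest, and no library of pure endothelial cells is at hand to judge them. Until that is settled, the changes of Id1, Vegfa or Acvrl1 cannot be assigned to endothelial cells.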
